A study of Oryza sativa with 24 samples.

How the data were processed

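RNA-seq values of 12 rice flag leaf libraries were used, 2 for each of 6 groups: the hybrid CY84 and the Fix generations T0 to T4. The authors deposited 1 table of FPKM (fragments per kilobase of gene scaled to the library's mapped fragments) with 1 column per library. The submitters' notes name FastQC, Trimmomatic 0.39, HISAT2 2.1.0, StringTie 1.3.4d, featureCounts 1.6.4, DESeq2 1.30.1, fastp and Bismark 0.23.0, and the step each was used for is not given in the sources used here, nor is the genome build. The 20 unnamed columns of the table were not used, and 12 bisulfite samples were not analysed here.

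Of 55801 listed genes, 26866 were at 0 in all libraries, and the 18871 with an FPKM of at least 1 in at least 2 libraries were tested. Read counts were not used here, so absolute depth is unknown and no counting interval is given. Relative depth was read from the most frequent ratio of low FPKM values between libraries. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean per group and a trended prior. This gave 6 residual degrees of freedom, and all groups shared 1 estimate of the spread. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were Fix T0 with CY84, Fix T1 to T4 each with Fix T0, Fix T4 with CY84, the mean of the Fix generations with CY84, a linear contrast over the generations, and an F test of any difference among them. They were chosen before the data were examined. The replicate numbers did not pair libraries across groups: after subtraction of group means, the correlation of equally numbered libraries was over 0.1 in 2 of 15 pairs of groups.

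Genes were named by a rule written before the data were examined. It took genes that passed, had a log2 difference of at least 1 (0.25 per generation for the linear contrast), a group mean of at least 5 FPKM and no overlap between the compared libraries, and ranked them by size. The first 10 each way were taken for Fix T0 with CY84, the Fix mean, Fix T4 with Fix T0 and the linear contrast, and the first 3 for the other comparisons. Where fewer than 5 passed, the 5 with the smallest p were named as not passing. For genes without a usable name, a pair each way was given, chosen after their values were seen, as were levels given to show the spread of single genes. Some genes that the rule names are not reported here.

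The table holds MSU identifiers and no gene names, and the annotation table used holds names and no MSU identifiers. Names were therefore paired with identifiers by hand from published rice nomenclature, which is a limit on every gene name and every list printed here. Of 333 paired genes, 197 names were found in the annotation and 187 of these on the chromosome of the identifier. After a check of gene order along the chromosome, 183 were kept as checked, 13 were dropped because the name lay elsewhere, and 4 because the identifier was not in the table. For 133 the name was not in the annotation, and of these only genes of lists written before the data were examined were used, among them PR1b, WRKY45, NAP, REC8, OSD1 and MTL. This left 200 usable names, of which 137 were tested. The rule of using later names only where checked, and the wider lists, were settled after first fits had been seen.

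Gene lists were tested with camera from limma at a preset correlation of 0.01, and with an estimated correlation, for lists with at least 5 tested members. This tests a list against the other genes, not against no change. Of 22 lists written before the data were examined, 46 of 168 entries could be paired with an identifier, and 4 lists could be tested: circadian clock, defence, flowering time and leaf senescence. In the 8 comparisons with a direction, 14 of their 32 tests passed, and 0 did with an estimated correlation. A further 26 lists were written after the identifiers were known, and 14 were tested. Among the 14, the wider defence and flowering lists also hold the members written before. Markers of anther, seed, root, meiosis and cell division were used as levels only.

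Replicate pairs were compared with all pairings of the libraries, and distances between generations with all 120 orders, both by exact permutation. On simulated data with no change, 3 and 1 genes passed for Fix T0 with CY84 and Fix T4 with Fix T0. Beside 200 genes changed 4-fold or 8-fold, 16 and 17 unchanged genes passed in the first comparison and 7 and 11 in the second. The simulated noise was independent between genes and of equal spread in all groups. It holds no shifts of whole libraries and no unequal pairs, so it does not measure false calls in the real libraries. Of 20 simulated lists the 1 that was moved passed and 0 others did. Alternatives were a pseudocount of 0.1, no filter, rescaling by median-of-ratios factors, a replicate block, leaving out each library in turn, fits of the compared groups alone, a straight line over the Fix libraries, Spearman distances and an estimated correlation. Leaving out the 4 libraries of Fix T1 and T2, and library weights, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with tables read by pandas 2.3.3 and numpy 2.4.6.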

Results

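Gene expression was measured by RNA-seq in flag leaves taken at heading from the indica-japonica hybrid rice Chunyou84, called CY84 here, and from its edited derivative, called Fix. The Fix line carries edits of REC8, PAIR1 and OSD1, which replace meiosis by a mitosis-like division, and of MTL. With these edits the line sets clonal seeds. The 6 groups were CY84, the founding Fix plant (Fix T0) and the diploid seed generations Fix T1 to Fix T4, with 2 libraries each and 12 libraries in all. CY84 and Fix T0 had been kept by their roots, and the seed generations had been grown from seed. Summed FPKM lay between 680768 in Fix T4 replicate 2 and 767790 in Fix T2 replicate 2, and between 22097 and 23731 of the 55801 listed genes had a value above 0 in a library. Total read numbers were not used here, but the spacing of the low values gives the libraries' relative depth: with CY84 replicate 1 set to 1, the shallowest was Fix T3 replicate 2 at 0.674, and the Fix T0 libraries stood at 0.713 and 0.876. Log2 differences are on the log2(FPKM + 1) scale, which understates changes of genes with low values. Nothing in the labels says that the replicates are separate plants, so a p measures only the spread between these samples.

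The 4 edited genes were close to the floor in flag leaves of every group, so they check neither the edits nor the labels. REC8, a meiotic cohesin, had at most 0.103 FPKM in any library, and PAIR1, needed for meiotic recombination, was listed at 0 in 10 libraries and at 0.0856 and 0.0697 in Fix T0. OSD1, a cell cycle regulator of meiosis, was listed at 0 in 11 libraries and at 0.521 in Fix T0 replicate 2, and MTL, a pollen phospholipase, lay between 0.105 FPKM in CY84 replicate 2 and 1.25 FPKM in Fix T4 replicate 1. Actin ACT1, a common reference gene, had 40.2 ± 0.552 FPKM in CY84 (SD, n = 2) and 47.9 ± 5.87 FPKM in the Fix libraries (SD, n = 10). Markers of other tissues were scarce: all 6 anther genes stayed below 1 FPKM in all 12 libraries, as did 3 of the 5 seed storage genes, 3 of the 5 root genes, 8 of the 11 meiosis genes and 8 of the 10 cell division genes. The highest root gene was LSI1, a silicon transporter, which reached 72.8 FPKM.

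Libraries of a group resembled each other more than libraries of different groups did on average. The mean distance, 1 minus Pearson r of log2(FPKM + 1) over 18871 genes, was 0.0392 within the 6 replicate pairs and 0.0540 over all pairings of the 12 libraries, of which 32 were as low (exact permutation test, one-sided, p = 0.00308). Fix T1 and Fix T2 were the loosest pairs, with r = 0.945 and r = 0.936, against 0.982 for CY84, 0.974 for Fix T0, 0.958 for Fix T3 and 0.970 for Fix T4. For 5 of the 12 libraries the nearest library was one of another group: both Fix T1 libraries, both Fix T2 libraries and Fix T4 replicate 2. Fix T1 replicate 2 was nearest to Fix T4 replicate 2 (r = 0.973), and it was also closer to both libraries of CY84 (0.958 and 0.956), Fix T0 (0.967 and 0.965) and Fix T3 (0.948 and 0.950) than to its own partner. In Fix T2 replicate 2 the 10 highest genes held 19.3% of the summed FPKM, against 13.2% to 17.5% in the other 11 libraries. The clock gene LHY stood at 11.7 FPKM in this library and at 19.6 to 68.2 FPKM in the other 11.

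**Figure D1:**
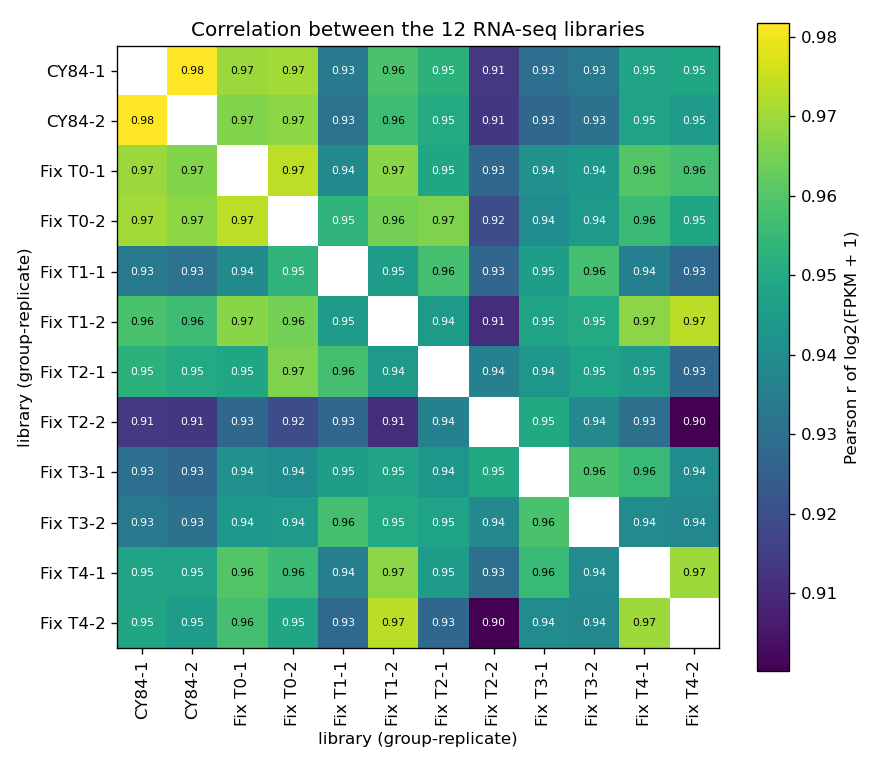
Pearson correlation of log2(FPKM + 1) over the tested genes for each pair of the 12 libraries, named by group and replicate, with colour running from low (dark) to high (bright). The CY84 pair reaches 0.982, while Fix T1 and Fix T2 pairs stay at 0.945 and 0.936.

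The comparison of Fix T0 with CY84 sets the edited founding plant against the hybrid, both kept in the same way. A difference here can belong to the edits or to the Fix T0 plant itself. No gene with a usable name passed the test, and 4 of the named genes nearest to it are given here as not passing. CKX2, a cytokinin oxidase, had 0.131 and 0.411 FPKM in CY84 and 11.4 and 9.21 FPKM in Fix T0 (log2 difference 3.15, SE 0.74, limma adjusted p = 0.360). LSI1 was at 19.1 ± 0.724 FPKM in CY84 and 42.1 ± 3.40 FPKM in Fix T0 (SD, n = 2 each). WRKY76, a defence regulator, was at 17.1 ± 1.62 against 2.12 ± 2.39 FPKM and the nitrate reductase NIA1 at 99.1 ± 26.3 against 46.9 ± 2.16 FPKM. Of 19 alternatives, CKX2 passed in 4, LSI1 in 2, and WRKY76 and NIA1 in 1 each. All 5 genes of the leaf senescence list (SGR, NYC1, NYC3, PAO and NAP) lay below CY84, with a median log2 difference of -0.54, and the list lay below the other genes, against which camera tests a list (camera adjusted p = 0.0106). Its adjusted p = 0.518 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Without CY84 replicate 2 its camera adjusted p was 0.113. The clock, flowering and defence lists did not pass in this comparison.

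Among genes without a usable name, 17 of the 18871 tested passed, 11 higher and 6 lower in Fix T0. LOC_Os03g02470 was listed at 0 and 0.232 FPKM in CY84 and stood at 24.6 and 20.5 FPKM in Fix T0. LOC_Os07g06834 had 1.33 and 0.355 FPKM in CY84 and 64.7 and 57.0 FPKM in Fix T0. LOC_Os07g04500 had 45.1 and 53.6 FPKM in CY84 and was listed at 0 in both Fix T0 libraries, and LOC_Os06g08041 had 14.3 ± 4.79 FPKM (SD, n = 2) and was likewise listed at 0 in both. In Fix T1 to T4 the means of LOC_Os07g04500 were 60.8, 67.8, 61.4 and 55.1 FPKM. Those of LOC_Os07g06834 were 12.6, 4.41, 4.48 and 3.80 FPKM. LOC_Os03g02470 and LOC_Os06g08041 stayed on the Fix T0 side of both CY84 libraries. Part of these differences was thus not kept in the later generations of the edited line. At an unadjusted p under 0.05 the numbers were 353 higher and 378 lower. On simulated data the fit recovered 0% of genes changed 2-fold, 92.5% of genes changed 4-fold and 99.5% of genes changed 8-fold in this comparison. With that noise, of equal spread in all groups, differences of 2-fold were not detectable. The count was 5 without CY84 replicate 2, 10 without Fix T0 replicate 1 and 36 without the 4 libraries of Fix T1 and T2, the last chosen after seeing the data.

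The mean of the 5 Fix generations was compared with CY84 to describe the edited line as a whole. CY84 and Fix T0 had been kept by their roots and the other 4 generations grown from seed, so this comparison mixes the edits with the way the plants were raised. PR1b and PBZ1 were higher and NIA1 was lower in Fix. PR1b, a pathogenesis-related protein, had 12.8 ± 0.254 FPKM in CY84 (SD, n = 2) and 271 ± 238 FPKM in Fix (SD, n = 10), a log2 difference of 3.84 (SE 0.56, limma adjusted p = 0.00942). PBZ1, a pathogenesis-related protein of the PR10 family, went from 129 ± 55.3 to 861 ± 492 FPKM, with a log2 difference of 2.54 (SE 0.38, limma adjusted p = 0.0108). In Fix T0 alone, where neither gene passed against CY84, PR1b stood at 62.7 ± 7.37 FPKM and PBZ1 at 248 ± 47.7 FPKM (SD, n = 2). NIA1 was at 99.1 ± 26.3 FPKM in CY84 and 36.2 ± 9.01 FPKM in Fix, a log2 difference of -1.44 (SE 0.24, limma adjusted p = 0.0169). LSI1 rose by a log2 difference of 1.22 (SE 0.23, limma adjusted p = 0.0271). For these 4 genes all 10 Fix libraries lay on the same side of both CY84 libraries, as the naming rule required.

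The lignin enzyme gene CAD2 and the phosphate transporter gene PHT1-1 also passed the adjusted threshold with log2 differences of 1.92 and 0.93, but their libraries overlapped between the groups. Of the 6 tested genes of the defence list, PR1b and PBZ1 passed over all genes. Adjusted over the list alone 4 did, 2 higher and 2 lower, and the list as a whole did not pass (camera adjusted p = 0.0696). The 5 leaf senescence genes lay below CY84 (median log2 difference -0.83) and the list below the other genes (camera adjusted p = 0.00365). This list had an adjusted p = 0.379 with an estimated correlation, 0 members passed over all genes and 4 passed adjusted over the list alone. NYC1, a chlorophyll b reductase, stood at 119 ± 5.06 FPKM in CY84 and 69.6 ± 21.9 FPKM in Fix, and the stay-green gene SGR at 28.5 ± 12.1 against 13.6 ± 10.8 FPKM. Of the lists written later, the phenylpropanoid list lay above the other genes (camera adjusted p = 6.71e-06, adjusted p = 0.110 with an estimated correlation, 2 of 5 members passing over all genes and 4 adjusted over the list alone).

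In total 141 genes passed in the mean of the Fix generations against CY84, 102 higher and 39 lower. The majority of higher genes did not hold throughout: 1010 were higher and 1468 lower at an unadjusted p under 0.05, 46 and 47 passed with no filter, 166 and 192 without Fix T1 replicate 2, and 819 and 1233 with library weights, chosen after seeing the data. LOC_Os03g02470 was listed at 0 and 0.232 FPKM in CY84 and ranged from 20.5 to 154 FPKM in Fix, and LOC_Os05g49240 had 19.4 and 26.8 FPKM in CY84 and at most 1.81 FPKM in Fix. Another scaling moved the median of all genes by 0.13 here, and the median fold change of all genes was -0.13 in the deposited values. The count was 18 without CY84 replicate 1, 10 without CY84 replicate 2, 79 without Fix T0 replicate 1, 237 without Fix T1 replicate 1, 358 without Fix T1 replicate 2, 246 without Fix T2 replicate 1 and 509 without the 4 libraries of Fix T1 and T2. Without CY84 replicate 2 the limma adjusted p was 0.263 for PR1b, 0.111 for PBZ1, 0.473 for LSI1 and 0.556 for NIA1, and without CY84 replicate 1 it was 0.173, 0.285, 0.435 and 0.115. LSI1 also lost its call without Fix T0 replicate 1 (limma adjusted p = 0.0688), Fix T0 replicate 2 (0.0602), Fix T4 replicate 1 (0.0634) or Fix T4 replicate 2 (0.0597), and on rescaling (0.0554). With no filter on low values the limma adjusted p was 0.0582 for PR1b, 0.0598 for PBZ1, 0.0663 for LSI1 and 0.0512 for NIA1.

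**Figure D2:**
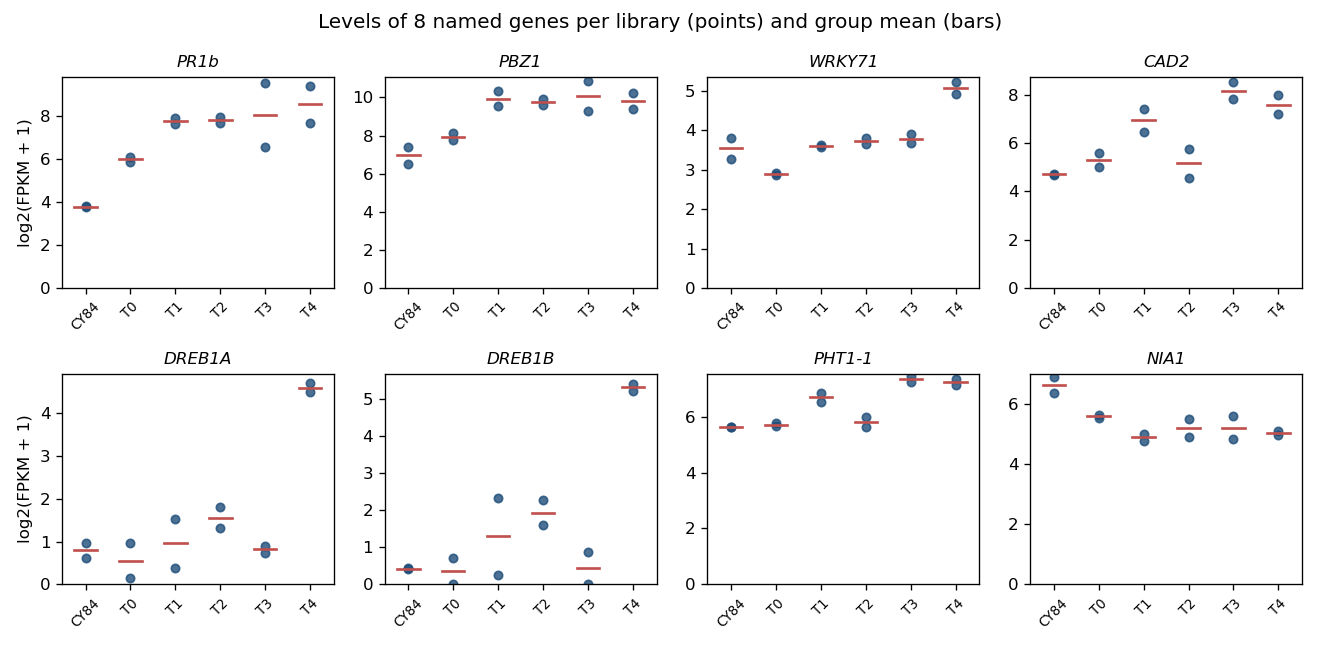
Level of 8 named genes as log2(FPKM + 1), with CY84 and Fix T0 to T4 on the horizontal axis, a point per library and a bar at the mean of the 2 libraries of a group. PR1b and PBZ1 lie lowest in CY84, NIA1 lies highest there, WRKY71 is at 33.2 FPKM in Fix T4 on average, and DREB1A and DREB1B reach 25.0 and 42.0 FPKM in Fix T4.

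Each seed generation was compared with the founding plant Fix T0 to find what differed after clonal reproduction. Fix T0 had been kept by its roots and the seed generations had not, so each of these comparisons also carries that difference. In Fix T1 no gene with a usable name passed. Among the nearest, none of them passing, were PHT1-1 with 103 ± 16.5 FPKM against 51.5 ± 2.88 FPKM in Fix T0 (SD, n = 2 each), PBZ1 with 1017 ± 379 against 248 ± 47.7 FPKM, the cytosolic glutamine synthetase GLN1-1 with 392 ± 51.4 against 216 ± 6.95 FPKM and CAD2 with 128 ± 58.2 against 38.9 ± 11.2 FPKM. Of the 6 defence genes 5 stood above Fix T0, and the list lay above the other genes (camera adjusted p = 0.0112, adjusted p = 0.412 with an estimated correlation). Without Fix T0 replicate 1 and without Fix T1 replicate 2 its camera adjusted p was 0.114 and 0.131. None of its 6 members passed over all genes and 1, PBZ1, passed adjusted over the list alone. Among all genes 15 passed, 8 higher and 7 lower, and 480 were higher and 472 lower at an unadjusted p under 0.05. LOC_Os03g18779 had 0.0716 and 0.0349 FPKM in Fix T0 and 28.2 and 18.7 FPKM in Fix T1, and LOC_Os05g08420 had 39.0 and 36.4 FPKM in Fix T0 and 2.27 and 2.34 FPKM in Fix T1. The count was 6 without Fix T0 replicate 1 and 152, 18 higher and 134 lower, without Fix T1 replicate 2. The LOC_Os05g08420 call was lost without Fix T0 replicate 1 (limma adjusted p = 0.0519).

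In Fix T2 the named genes again did not pass, and those nearest to the threshold were mostly lower than in Fix T0. LHY, a morning clock gene, had 67.0 ± 1.67 FPKM in Fix T0 and 18.9 ± 10.2 FPKM in Fix T2 (SD, n = 2 each). The phenylpropanoid enzyme 4CL3 had 46.5 ± 7.24 against 17.1 ± 4.88 FPKM, the senescence regulator NAP 33.6 ± 4.77 against 9.90 ± 1.01 FPKM and the starch synthase WX 5.85 ± 0.182 against 2.23 ± 0.801 FPKM. PBZ1 had 248 ± 47.7 FPKM in Fix T0 and 866 ± 145 FPKM in Fix T2. Of 17 alternatives, LHY and 4CL3 passed in 3 each, and NAP, WX and PBZ1 in 0. The clock list (median log2 difference -0.80, camera adjusted p = 0.0305) and the leaf senescence list (-1.01, camera adjusted p = 0.0334) lay below the other genes by the limma set test. The defence list (0.48, camera adjusted p = 0.0205) and the flowering list (0.29, camera adjusted p = 0.0305) lay above them. With an estimated correlation the adjusted p = 0.365 for clock and for senescence, and the adjusted p = 0.266 for defence and for flowering. Over all genes 0 members of these lists passed. Adjusted over the list alone 2 clock genes and 2 senescence genes were lower, 1 defence gene was higher, and 1 flowering gene went each way.

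Fix T2 against Fix T0 gave 17 genes, 4 higher and 13 lower. At an unadjusted p under 0.05 it gave 362 higher and 3222 lower, beside a median log2 difference of all genes of -0.28. Rescaling the libraries by median-of-ratios factors moved that median by 0.31 and the share of higher genes among those passing from 23.5% to 50%, and it ended the list calls (camera adjusted p = 0.0652 for each of the 4 lists). LOC_Os07g04500, listed at 0 in Fix T0, had 46.7 and 89.0 FPKM in Fix T2, and LOC_Os07g23510 had 12.2 and 13.3 FPKM in Fix T0 and was listed at 0 in Fix T2. The count was 1066 without Fix T2 replicate 1, 397 without Fix T1 replicate 1, 367 without Fix T1 replicate 2, 9 without Fix T2 replicate 2, 9 without either CY84 replicate, 7 without Fix T0 replicate 2 and 3 without Fix T0 replicate 1. Without Fix T2 replicate 2 the camera adjusted p was 0.872 for clock and 0.170 for defence and for senescence. Without Fix T2 replicate 1 it was 0.503 for flowering and 0.0871 for senescence. Without Fix T0 replicate 1 it was 0.0940 for flowering and 0.0526 for defence and for senescence, without Fix T0 replicate 2 it was 0.0651 for clock and for senescence, and without Fix T1 replicates 1 and 2 it was 0.0608 and 0.0602 for senescence.

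Fix T3 exceeded Fix T0 in a lignin enzyme gene and in a phosphate transporter gene. CAD2, a cinnamyl alcohol dehydrogenase, had 38.9 ± 11.2 FPKM in Fix T0 and 295 ± 104 FPKM in Fix T3 (SD, n = 2 each), a log2 difference of 2.87 (SE 0.44, limma adjusted p = 0.0172). PHT1-1 had 51.5 ± 2.88 and 161 ± 18.1 FPKM, a log2 difference of 1.62 (SE 0.23, limma adjusted p = 0.0105). 4CL3 and GLN1-1 did not pass, at 131 ± 0.132 and 438 ± 12.4 FPKM in Fix T3. Of 18 alternatives, 4CL3 passed in 5 and GLN1-1 in 4. All 6 defence genes stood above Fix T0 (median log2 difference 1.54), and the list lay above the other genes (camera adjusted p = 4.72e-05, adjusted p = 0.122 with an estimated correlation), with 0 members passing over all genes and 3 adjusted over the list alone. PR1b showed how unequal the pair was, with 735 FPKM in replicate 1 and 92.9 FPKM in replicate 2. Clock, flowering and senescence lists did not pass.

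The Fix T3 comparison gave 55 genes, 41 higher and 14 lower, while the median of all genes was -0.19 and moved by 0.20 on rescaling. The count was 8 without Fix T0 replicate 1, 6 without Fix T0 replicate 2, 19 without Fix T3 replicate 1, 335 (142 higher and 193 lower) without Fix T1 replicate 1, 329 (141 and 188) without Fix T1 replicate 2 and 84 without either Fix T2 replicate. It was 152 on rescaling and 1628, 457 higher and 1171 lower, without the 4 libraries of Fix T1 and T2. CAD2 and PHT1-1 lost their calls without Fix T0 replicate 1 (limma adjusted p = 0.102 and 0.150), without Fix T0 replicate 2 (0.256 and 0.135) and without Fix T3 replicate 1 (0.141 and 0.0644). PHT1-1 also lost its call without Fix T3 replicate 2 (limma adjusted p = 0.0724), and CAD2 with no filter (0.0797).

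Fix T4 differed from Fix T0 mainly by genes that rose. DREB1B and DREB1A, transcription factors of the cold and dehydration response, rose most among named genes. DREB1B was listed at 0 and 0.632 FPKM in Fix T0 and had 42.0 and 36.3 FPKM in Fix T4 (log2 difference 4.97, SE 0.56, limma adjusted p = 0.00165). DREB1A had 0.525 ± 0.587 and 23.3 ± 2.52 FPKM (SD, n = 2 each; log2 difference 4.04, SE 0.41, limma adjusted p = 0.000887). The jasmonate repressor gene JAZ10 rose from 0.790 ± 0.120 to 12.1 ± 1.41 FPKM and the defence regulator WRKY71 from 6.38 ± 0.201 to 33.2 ± 5.06 FPKM, with limma adjusted p = 0.00791 and 0.00202. CYP99A3, an enzyme of momilactone phytoalexin synthesis, rose from 1.34 ± 0.459 to 8.74 ± 1.12 FPKM and CAD2 from 38.9 ± 11.2 to 198 ± 72.7 FPKM, both with limma adjusted p = 0.0295. PHT1-1 rose from 51.5 ± 2.88 to 149 ± 15.2 FPKM (limma adjusted p = 0.00920). No named gene fell by the same rule.

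As a group, all 6 defence genes of the first list lay above Fix T0 in Fix T4 (median log2 difference 1.62), and the list lay above the other genes (camera adjusted p = 0.00216, adjusted p = 0.271 with an estimated correlation). None passed over all genes and 3 passed adjusted over the list alone. A wider defence list of 15 genes, written later, had all 15 members above Fix T0 and lay above the other genes (camera adjusted p = 5.77e-10, adjusted p = 0.0984 with an estimated correlation), of which WRKY71 and CYP99A3 passed over all genes and 9 passed adjusted over the list alone. All 8 jasmonate genes lay above Fix T0 (median log2 difference 1.40) and the list above the other genes (camera adjusted p = 3.38e-06, adjusted p = 0.0849 with an estimated correlation), with JAZ10 passing over all genes and 5 adjusted over the list alone. The phenylpropanoid list had a median log2 difference of 1.40 and camera adjusted p = 3.11e-05 (adjusted p = 0.0896 with an estimated correlation). Clock, flowering and senescence lists did not pass, and 0 of their members passed over all genes.

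In total 199 genes passed in Fix T4 against Fix T0, 185 higher and 14 lower. LOC_Os01g09220 had 0.963 and 1.77 FPKM in Fix T0 and 61.2 and 52.0 FPKM in Fix T4, and LOC_Os07g06834 had 64.7 and 57.0 FPKM in Fix T0 and 4.26 and 3.34 FPKM in Fix T4. The median log2 difference of all genes was 0.16 and moved by -0.17 on rescaling, so a log2 difference near that size carries no direction. The count fell to 30, 32, 40 and 31 without Fix T0 replicate 1, Fix T0 replicate 2, Fix T4 replicate 1 and Fix T4 replicate 2, was 121 and 123 without CY84 replicates 1 and 2, and was 313 and 314 without Fix T1 replicates 1 and 2. DREB1A, DREB1B and WRKY71 passed with each of these libraries left out, while JAZ10, CAD2, CYP99A3 and PHT1-1 did not pass without any single one of the 4 Fix T0 and T4 libraries (highest limma adjusted p = 0.124, 0.375, 0.305 and 0.145). CAD2 and CYP99A3 were also lost without either CY84 replicate (highest limma adjusted p = 0.0577 and 0.0539), on rescaling (0.0725 and 0.0839), with a pseudocount of 0.1 (0.0584 and 0.0537) and with no filter (0.113 and 0.103). The count was 420 without the 4 libraries of Fix T1 and T2, chosen after seeing the data. LOC_Os01g09220 lost its call with a pseudocount of 0.1 (limma adjusted p = 0.0751), with no filter (0.0872) and without Fix T0 replicate 1 (limma adjusted p = 0.141), Fix T0 replicate 2 (0.142), Fix T4 replicate 1 (0.111) or Fix T4 replicate 2 (0.151), and LOC_Os07g06834 lost its call without Fix T0 replicate 1 (0.0588) or Fix T4 replicate 2 (0.0625).

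Fix T4 against CY84 compares the last clonal generation with the unedited hybrid. Among named genes, DREB1B (0.340 ± 0.0154 FPKM in CY84 and 39.1 ± 3.98 FPKM in Fix T4, SD, n = 2 each), PR1b (12.8 ± 0.254 and 438 ± 329 FPKM) and DREB1A (0.756 ± 0.298 and 23.3 ± 2.52 FPKM) rose most, with log2 differences of 4.90, 4.76 and 3.79 and limma adjusted p = 0.00137, 0.00619 and 0.000720. NIA1 was the named gene that fell, from 99.1 ± 26.3 to 31.4 ± 2.31 FPKM (log2 difference -1.60, SE 0.31, limma adjusted p = 0.0201). In the defence list PR1b and PBZ1 passed over all genes and 3 of 6 passed adjusted over the list alone, while the list had camera adjusted p = 0.0596. The leaf senescence list (median log2 difference -0.35) and the flowering list (-0.30) lay below the other genes, whose change had the median 0.12 over all genes, both with camera adjusted p = 0.0161 and both with an adjusted p = 0.326 with an estimated correlation. The senescence call was lost without Fix T4 replicate 1 (camera adjusted p = 0.260) and the flowering call without Fix T4 replicate 2 (0.0992). Of 5 phenylpropanoid genes 3, with 4CL3 and CAD2 among them, passed over all genes and adjusted over the list alone, and the list had camera adjusted p = 1.44e-06 (adjusted p = 0.0942 with an estimated correlation).

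For Fix T4 against CY84, 355 genes passed, 317 higher and 38 lower. LOC_Os03g02470 was listed at 0 and 0.232 FPKM in CY84 and had 70.5 and 77.0 FPKM in Fix T4 (log2 difference 6.07). LOC_Os01g09220 had 0.936 and 0.747 FPKM in CY84 and 61.2 and 52.0 FPKM in Fix T4 (log2 difference 4.96). With no filter LOC_Os01g09220 did not pass (limma adjusted p = 0.0507). LOC_Os03g54130 had 13.3 and 30.6 FPKM in CY84 and was listed at 0 and 0.299 FPKM in Fix T4. The count was 92 without CY84 replicate 1, 34 without CY84 replicate 2, 100 without Fix T4 replicate 1, 61 without Fix T4 replicate 2 and 719 without the 4 libraries of Fix T1 and T2, and the median of all genes (0.12) moved by -0.12 on rescaling. PR1b did not pass without CY84 replicate 1 (limma adjusted p = 0.0588), CY84 replicate 2 (0.0766) or Fix T4 replicate 1 (0.0634), and NIA1 did not pass without any single one of the 4 libraries (highest limma adjusted p = 0.276) or with no filter (0.0603).

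**Figure D3:**
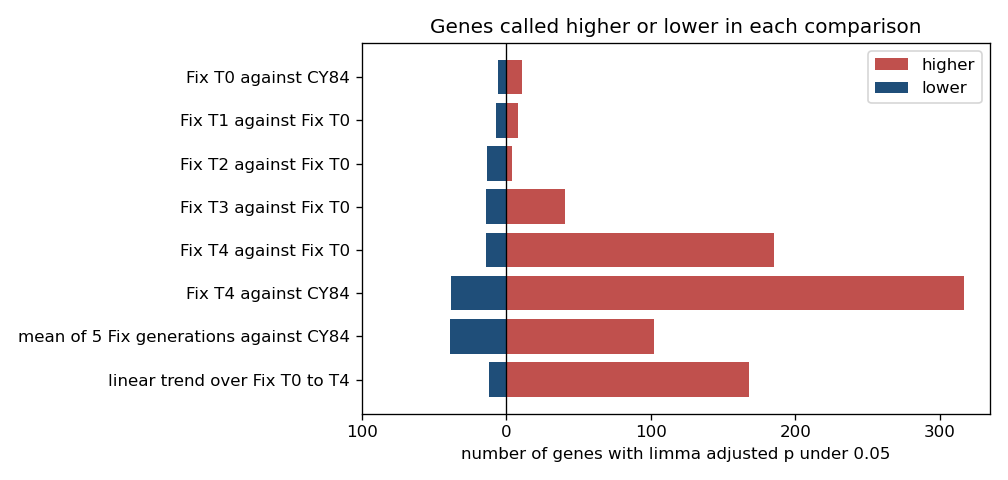
Number of genes with a limma adjusted p under 0.05 that were higher (right of 0) or lower (left of 0) in each of the 8 comparisons that have a direction. Fix T4 against CY84 has 317 higher and 38 lower genes, and Fix T0 against CY84 has 11 higher and 6 lower.

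The 5 Fix generations together were tested for any difference among them. The limma F test gave the smallest p among named genes for DREB1A (adjusted p = 0.00279) and DREB1B (0.00624), and it also passed for 4CL3 (0.00760), PHT1-1 (0.00858), CAD2 (0.0122), WRKY71 (0.0122) and JAZ10 (0.0205). 4CL3 went from 46.5 ± 7.24 FPKM in Fix T0 to 17.1 ± 4.88 FPKM in Fix T2 and 131 ± 0.132 FPKM in Fix T3 (SD, n = 2 each). In all 227 of 18871 genes passed, while 4211 had an unadjusted p under 0.05. The count was 107 without either CY84 replicate, 65 and 53 without Fix T0 replicates 1 and 2, 1961 and 2209 without Fix T1 replicates 1 and 2, 123 without Fix T2 replicate 2, 88 and 54 without Fix T4 replicates 1 and 2, and 2830 without the 4 libraries of Fix T1 and T2. DREB1B was lost without Fix T4 replicate 1 (limma adjusted p = 0.0574) or replicate 2 (0.0597), CAD2 without Fix T0 replicate 2 (0.0589), and WRKY71 and JAZ10 without any single one of the Fix T0 and T4 libraries (highest 0.156 and 0.199). With a pseudocount of 0.1 the limma adjusted p was 0.0766 for DREB1B and 0.0777 for JAZ10, and with no filter it was 0.0779 for CAD2 and 0.104 for JAZ10.

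Among named genes, the linear contrast over the generations ranked DREB1B (0.91 log2 units per generation, SE 0.13, limma adjusted p = 0.00790) and DREB1A (0.79, SE 0.09, limma adjusted p = 0.00311) first. They were followed by MAS, a momilactone synthase gene, with 0.75 per generation, then JAZ10 with 0.63, CAD2 with 0.58, CYP99A3 with 0.51, WRKY45 and WRKY71 with 0.46 each and PHT1-1 with 0.37. No named gene fell. All 6 defence genes had a slope above 0 (median 0.42), and the list lay above the other genes (camera adjusted p = 0.000138, adjusted p = 0.149 with an estimated correlation). WRKY45 passed over all genes and 4 defence genes passed adjusted over the list alone. The phenylpropanoid and jasmonate lists kept their calls with an estimated correlation (adjusted p = 0.0444 for both). The clock and flowering lists lay below the other genes with camera adjusted p = 0.0420 each, which became adjusted p = 0.553 and 0.304 with an estimated correlation. Both were lost without Fix T0 replicate 2 (camera adjusted p = 0.195), Fix T3 replicate 1 (0.0512) or Fix T3 replicate 2 (0.0646). Clock was also lost without Fix T1 replicate 2 (0.109) or Fix T4 replicate 1 (0.349), and flowering without Fix T1 replicate 1 (0.177) or Fix T4 replicate 2 (0.322). With no filter both had camera adjusted p = 0.0852, and on rescaling flowering had 0.0660.

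The linear contrast gave 180 genes, 168 higher and 12 lower, but a straight line fitted to the 10 Fix libraries alone gave 0 genes by limma, with DREB1A at adjusted p = 0.391. LOC_Os07g04500, without a usable name, had a larger slope than any named gene (1.16 log2 units per generation, limma adjusted p = 6.96e-06). It was listed at 0 in both Fix T0 libraries and had means of 60.8, 67.8, 61.4 and 55.1 FPKM in Fix T1 to T4. That is a step after Fix T0, not a steady rise. Among other single genes, DREB1A stood at 2.52 FPKM or less in all 8 Fix libraries before Fix T4, and CAD2 stood at 128 ± 58.2 FPKM in Fix T1, 38.0 ± 21.8 FPKM in Fix T2 and 295 ± 104 FPKM in Fix T3 (SD, n = 2 each). The steps between successive seed generations were not tested. The count was 105 without either CY84 replicate, 23 and 20 without Fix T0 replicates 1 and 2, 453 without Fix T1 replicate 2, 101 without Fix T3 replicate 1, 33 and 24 without Fix T4 replicates 1 and 2, and 449 without the 4 libraries of Fix T1 and T2. Of the 9 genes named here for this contrast only DREB1A passed with each library left out. DREB1B was lost without Fix T0 replicate 1 (limma adjusted p = 0.0705), Fix T4 replicate 1 (0.0570) or Fix T4 replicate 2 (0.0665). The other 7 were each lost without Fix T0 replicate 1, Fix T0 replicate 2 or Fix T4 replicate 2, with a highest limma adjusted p of 0.233 for MAS, 0.115 for JAZ10, 0.186 for CAD2, 0.185 for CYP99A3, 0.311 for WRKY45, 0.0666 for WRKY71 and 0.0949 for PHT1-1. Without Fix T4 replicate 1 all of these 7 but WRKY71 and PHT1-1 were lost, MAS was also lost without either CY84 replicate (highest 0.0556), and WRKY45 without either CY84 replicate (highest 0.0893), Fix T1 replicate 1 (0.0615) or Fix T3 replicate 1 (0.0795). With a pseudocount of 0.1 the limma adjusted p was 0.113 for DREB1B, 0.0816 for MAS, 0.0509 for JAZ10 and 0.0807 for WRKY45. With no filter it was 0.0511 for DREB1B, 0.134 for MAS, 0.0571 for JAZ10, 0.0927 for CAD2 and for CYP99A3, and 0.159 for WRKY45, and on rescaling it was 0.0656 for WRKY45. The distance between generation means did not grow with the number of generations between them (Spearman rho = 0.14 and Pearson r = 0.02 over 10 distances, exact permutation test over 120 orders, two-sided, p = 0.683). Fix T2 and Fix T4 were furthest apart, at a distance of 0.0520, and Fix T0 and Fix T1 nearest, at 0.0244.

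Other lists, written after the gene identifiers were known, were tested in the same way, but not on rescaled values, and none of the calls given here held with an estimated correlation. Above and below mean against the other genes in this paragraph. Nitrogen genes lay below in Fix T4 against CY84 (camera adjusted p = 0.000473, adjusted p = 0.173 with an estimated correlation), with NIA1 the member that passed over all genes. Phosphate starvation genes lay above in the mean of the Fix generations against CY84 (0.0231 and 0.308), with PHT1-1 the member that passed. Antioxidant enzymes lay above in that mean (0.0146 and 0.236), heat shock genes above in Fix T2 against Fix T0 (0.0118 and 0.585) and chlorophyll synthesis genes above in Fix T2 against Fix T0 (0.0112 and 0.660), but below in Fix T4 against Fix T0 (0.0322 and 0.462). The wider flowering list lay below in Fix T4 against CY84 (0.0145 and 0.610), and the yield and plant architecture list above in Fix T0 against CY84 (0.0185 and 0.237) but below in Fix T4 against Fix T0 (0.0239 and 0.127). The lists of DNA methylation and chromatin genes, abscisic acid and dehydration, iron, and sucrose and starch passed in none of the 8 comparisons. For Fix T4 against Fix T0 their camera adjusted p was 0.603, 0.648, 0.832 and 0.346. Of the 112 tests of the 14 later lists that were tested, 34 passed, 2 of them with an estimated correlation.

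The median log2 difference was computed for each chromosome, since a gained or lost chromosome would shift its genes together. In Fix T4 against Fix T0 the median log2 differences of the 12 chromosomes lay between 0.15 on chromosome 12 and 0.17 on chromosome 9. In Fix T0 against CY84 they lay between -0.07 on chromosome 4 and -0.01 on chromosome 11. The widest range was in Fix T3 against Fix T0, 0.11 log2 units from -0.26 on chromosome 12 to -0.15 on chromosome 9.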

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

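The tests of explanations in this part, and the comparison of Fix T4 with the other seed generations, were chosen only after the results were seen.

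DREB1A and DREB1B differed between seed generations in their change from Fix T0. Their change in Fix T4 exceeded the mean change of Fix T1, T2 and T3 by 3.48 and 4.10 log2 units (SE 0.33 and 0.46, limma adjusted p = 0.000731 and 0.00222). The same difference was 2.35 for JAZ10, 1.37 for WRKY71, 1.86 for the jasmonate synthesis gene AOS2 and 1.35 for JAZ12 (limma adjusted p = 0.0110, 0.0139, 0.0379 and 0.0470). It passed in 150 of 18871 genes, 146 of them higher in Fix T4. The median absolute log2 change of the 9 clock genes from Fix T0 was 0.226, 0.803 and 0.732 in Fix T1, T2 and T3 and 0.108 in Fix T4. Time of day at harvest was not tested for this comparison and stays open. Groups of 2 libraries are too small for a test of single outlying libraries.

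For the 185 genes that rose in Fix T4 over Fix T0, scaling as the whole source is argued against by its size. Rescaling moved the median of all genes by -0.17, while each of the 185 had risen by at least 1 log2 unit. All 199 genes that passed in this comparison had changed at least 2-fold, so that lower limit came with the calling. The sizes thus bear on how large the changes are, not on how many calls scaling made. That 185 of the 185 kept a log2 change of at least 1 in rescaled values adds little, since they were picked in deposited values. Of the 185, 125 still passed on rescaling, so scaling bears on part of the calls. An even build-up over generations, which needs a share of about 0.5 of the change by Fix T2, stays open. In genes picked with 1 library each of Fix T4 and Fix T0 and measured with the other, the median share by Fix T2 was 0 and 0.162 in deposited values. In rescaled values it was 0.203 and 0.277, and the highest upper quartile was 0.622, above 0.5. All 4 medians lay below 0.5. Among the 185 genes the median share was 0.396 by Fix T1, 0.112 by Fix T2 and 0.521 by Fix T3. So the median share did not climb at each generation, in genes picked with these same Fix T0 and T4 libraries. The Fix T1 share averages 2 unlike libraries. At 559 genes that set Fix T4 apart from Fix T0, T2 and T3, Fix T1 replicate 1 stood at a median of -0.0893 and replicate 2 at 0.724. That scale runs from 0 at Fix T0, T2 and T3 to 1 at Fix T4. The drop from Fix T1 to Fix T2 may thus rest on Fix T1 replicate 2, whose label stays open. The quartiles give the spread between genes, not the uncertainty of a median, so they do not settle an even build-up. Time of day at harvest cannot be told apart from generation: the clock gene LHY changed by 0.70 in absolute log2 units (0.696), less than the 1.88 between Fix T2 and Fix T0. The median absolute change of the 9 clock genes was 0.108, the smallest of the 5 comparisons for which it was computed, and the next largest change was that of TOC1 at 0.25. These values go against a large shift in time of day between Fix T4 and Fix T0 but leave LHY open, and harvest times are not given in the sources used here. Fix T0 was kept by its roots and Fix T4 was grown from seed, a difference that goes with generation here and was not tested. Fix T1 to T3 were grown from seed too, so it does not by itself set Fix T4 apart from them. A response of the plants to weather, pests or handling may also have differed between groups and was not tested, and neither was a biological difference of the generation itself.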

How the results depend on the processing

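Leaving out the 4 libraries of Fix T1 and T2, and library weights, were chosen only after the results were seen. The cause was not tested for the changes below, except where fewer libraries or genes enter, or a pair leaves the shared estimate of the spread, by construction.

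With a pseudocount of 0.1 the count of genes that passed was 8 for Fix T1, 11 for Fix T2 and 72 for Fix T4 against Fix T0, 56 for the linear contrast and 114 for the F test, and the widest chromosome range was 0.174. With no filter, which tests more genes, the count was 33 for Fix T0 and 220 for Fix T4 against CY84, 93 for the Fix mean, 112 for Fix T4 against Fix T0, 73 for the linear contrast and 105 for the F test. The widest chromosome range was then 0.0733, and the correlation of distance with generations apart reversed to -0.03 (-0.0318). Rescaling gave 152 for Fix T3 against Fix T0, 138 for the F test and a chromosome range of 0.131.

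With a replicate block, although the numbers do not pair the libraries, the count was 11 for Fix T2 against Fix T0 and 139 for the F test, and within 1.5 times the reported count in the other comparisons. The block also ended the calls of CYP99A3 in Fix T4 against Fix T0 (limma adjusted p = 0.0505) and of WRKY45 in the linear contrast (limma adjusted p = 0.0727). Fits of fewer libraries gave 421 for Fix T4 against Fix T0 from their 4 libraries and 107 for the F test from the 10 Fix libraries. The straight line over the Fix libraries gave 0 genes. Of the 14 list calls 0 held with an estimated correlation.

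Without the 4 libraries of Fix T1 and T2 the count was 36 for Fix T0, 719 for Fix T4 and 509 for the Fix mean against CY84, 1628 for Fix T3 and 420 for Fix T4 against Fix T0, 449 for the linear contrast and 2830 for the F test. Library weights gave 214 for Fix T0, 1328 for Fix T4 and 2052 for the Fix mean against CY84, 9 for Fix T1, 751 for Fix T3 and 650 for Fix T4 against Fix T0, 374 for the linear contrast and 744 for the F test.

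Leaving out 1 library at a time assumes that a lone library varies like the other groups. It also takes the spread within that pair out of the estimate that all groups share. Where the group is not part of a comparison, the fold changes stay as they were. The count then moves through the shared spread alone, much alike whichever library of the pair is left out. Such a change reflects unequal spread between groups, not the pull of that single library. Fix T0 against CY84 ranged from 5 without CY84 replicate 2 to 22 without Fix T1 replicate 2. Against Fix T0, Fix T1 ranged from 6 without Fix T0 replicate 1 to 152 without Fix T1 replicate 2, and Fix T2 from 3 without Fix T0 replicate 1 to 1066 without Fix T2 replicate 1. Fix T3 ranged from 6 without Fix T0 replicate 2 to 335 without Fix T1 replicate 1, and Fix T4 from 30 without Fix T0 replicate 1 to 314 without Fix T1 replicate 2. Fix T4 against CY84 ranged from 34 without CY84 replicate 2 to 502 without Fix T1 replicate 1, and the Fix mean from 10 without CY84 replicate 2 to 358 without Fix T1 replicate 2. The linear contrast ranged from 20 without Fix T0 replicate 2 and the F test from 53 without it, to 453 and 2209 without Fix T1 replicate 2. List calls ranged from 10 without Fix T0 replicate 2 to 17 without Fix T4 replicate 2, and the chromosome range from 0.0971 to 0.146.

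The correlation of distance with generations apart ranged from -0.203 to 0.331. It reversed without Fix T0 replicate 2 (-0.0318), Fix T1 replicate 1 (-0.0953), Fix T2 replicate 1 (-0.0953), Fix T2 replicate 2 (-0.0763) and Fix T3 replicate 1 (-0.203), and none of these passed. The replicate pairs were closer than other pairings with every alternative run, with exact one-sided p between 0.00135 and 0.00414. No named gene reversed its direction, and DREB1A, DREB1B and WRKY71 in Fix T4 against Fix T0 passed with each of the 19 alternatives run for them. Relative depth differed by up to 1.41 times within a pair, and on simulated data 0% of genes changed 2-fold were recovered for Fix T0 against CY84 and for Fix T4 against Fix T0.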

Other observations

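All tests in this part were chosen only after the results were seen.

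In 6 genes both Fix T0 libraries stood apart from the other 10, below 0.1 FPKM against at least 1 FPKM, or the reverse. LOC_Os07g04500 and LOC_Os01g05540 were listed at 0 in Fix T0 alone, and 4 genes reached 1 FPKM in both Fix T0 libraries and stayed below 0.1 FPKM in the other 10. Of these 4, LOC_Os07g23510 (12.2 and 13.3 FPKM in Fix T0), LOC_Os05g50390 and LOC_Os03g31390 were listed at 0 in the other 10, and LOC_Os03g30740 stood at 0.0599 in Fix T2 replicate 2 and 0.0884 in Fix T3 replicate 2. These genes were singled out after their values were seen. Of 60 pairs of libraries from different groups 0 gave as many and the highest gave 1. This cannot decide whether such genes arise by chance, since such a pair scores only where both libraries differ from their own partners. Among replicate pairs, CY84 gave 3 such genes and the pairs of Fix T1 to T4 gave 0, so Fix T0 was not the only group with some. Low sequencing depth of the Fix T0 libraries is argued against for the 4 genes that were higher there. For the 2 listed at 0 it is argued against by Fix T3 replicate 2, which was shallower (0.674 against 0.713 and 0.876) and held LOC_Os07g04500 at 64.2 and LOC_Os01g05540 at 3.88 FPKM. That 1 chromosome segment that differs in the Fix T0 plant holds them is argued against, since 0 of the 6 genes had another within 20 listed loci. By these limits CY84 stood with the seed generations in these genes. A stable change in the founding plant that clonal seed passed on would not leave this pattern. What set the Fix T0 libraries apart was not tested, biological or not, and Fix T0 is the baseline for each seed generation.

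Fix T1 replicate 2 lay nearer to the Fix T4 libraries than to Fix T1 replicate 1, as it did to the libraries of CY84, Fix T0 and Fix T3, and 5 of 12 libraries were nearest to one of another group. A difference in depth as the source is argued against, since 2 replicate pairs, CY84 and Fix T0, had a higher correlation with a larger depth ratio (1.41 and 1.23 against 1.17). The median-of-ratios factor was 1.19 in Fix T1 replicate 2 and 0.868 in its partner. It was 1.19 and 1.29 in Fix T4, 1.04 to 1.14 in CY84 and Fix T0, and 0.727 to 0.914 in Fix T2 and T3. Whether the resemblance goes with this property of the libraries was not tested. For Fix T1 replicate 2 a wrong label cannot be told apart from a real difference. At 500 genes picked with 1 Fix T4 library against Fix T0, T2 and T3, its median position was 0.583 and 0.587 on a scale from 0 at these generations to 1 at that library. The Fix T4 library left out stood higher both ways round, at 0.639 in the lower case, and libraries left out of Fix T0, T2 and T3 stood at 0.276 to 0.710 at genes of their own group, so the positions lie within those of true members. Against the 2 Fix T4 libraries 57 and 36 of its genes were at least 4-fold apart and within 2-fold of Fix T1 replicate 1, more than the 17 of each Fix T4 library against its partner but fewer than the highest of other groups, 180 in Fix T2 replicate 1. Single genes also went against a wrong label, chosen after their values were seen: DREB1A had 1.90 FPKM against 25.0 and 21.5 in Fix T4, and LOC_Os05g08420 had 2.34 against 31.5 and 40.4, with 2.27 in its partner. A few genes do not decide it, since replicates of a group also differed 4-fold or more in single genes, and it stays open. Without Fix T1 replicate 2 the Fix T1 count was 152 in place of 15.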
